A study of Mus musculus with 6 samples.

How the data were processed

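RNA from the dissected nasal conchae of 6 mice, 3 controls and 3 carrying an inducible sFlt1 transgene, was sequenced as bulk libraries made from 200 ng of total RNA per mouse, per the labels' protocols. All mice are labelled c57Bl6/ICR crossbred. Per the submitters' processing notes, the tools named were cutadapt 3.5, TopHat2 2.2.1, HTSeq 2.0.1 and DESeq2 1.26.0, and the genome build was GRCm39. The alignment, strand and counting settings are not given in the sources used here. The deposited gene table holds raw read counts per Ensembl gene, not normalized, in 55414 entries, of which 6250 carried no values and were left out. The authors' table also gives log2 fold changes and adjusted p-values from DESeq2, per the file headers. Another deposited table repeats the counts of 1162 olfactory receptor genes, and another those of 54 marker genes that the authors grouped by cell type. The last deposited table holds receptor scores, which are counts that the authors scaled by 1 factor per sample and rounded, with log2 fold changes and p-values made from them, per the file headers. The basis of that factor is not given in the sources used here. The repeated counts were checked against the gene table, and 0 entries differed. Another 24 columns of per-sample normalized values were not used here. Each column was matched to its mouse by the spreadsheet column letters given in the sample descriptions.

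Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr on group, no covariate), with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. The filter left 19899 genes, 1028 of them receptors. Receptors were those in the authors' receptor table, whose summed counts over the 6 libraries were 10 or more. Another 252 genes with receptor symbols had summed counts of 9 or fewer and were outside it. Many receptors are close paralogs and 66 are pseudogene models, so reads shared between near-identical copies make single receptor values uncertain. Differences in receptor sequence between the crossbred mice were not examined. A further fit used receptors alone, with library sizes set to the summed receptor counts, and tested 1059 receptors. Class I receptors were the 128 receptors on chromosome 7 between positions 102125786 and 105018562 (GRCm39, from the deposited table). This block is bounded by the first and last receptor with a family synonym of MOR1 to MOR42 in a RefSeq table of the assembly GRCm38.p6, from which only names were taken. Of all receptors, 1133 had a MOR family synonym of any number there.

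Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 32 lists of at least 3 tested members. They were tested again with an estimated correlation and with fry. CPM values are relative to TMM-scaled library sizes. Errors are SD over 3 mice unless given as SE, and the SE of a log2 fold change is the estimate divided by the square root of the F statistic. Values per mouse were compared by exact permutation over the 20 assignments of 3 against 3, two-sided, for which the smallest p is 0.1. Receptor detection was the expected number of receptors seen after thinning each library to 74429 receptor counts. Intervals of shares are 95% Wilson intervals and cover counting error only. Library totals ranged from 28832424 to 46444862 counts. No pair of libraries agreed within sampling noise, as the closest pair, control replicates 1 and 2, had a chi-square of 83.9 per degree of freedom. The next closest pair lay across the groups, control replicate 1 and sFlt1 replicate 2, at 102.9.

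The tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Flt1 and 6 markers of mature and immature neurons. Outside the receptors it named up to 8 higher and 8 lower genes by fold that passed, with a mean CPM of 2 or more and no overlap between groups. It named the 5 higher and 5 lower receptors with the smallest p in each fit, and the members of each list with the smallest p and the highest mean CPM. As no gene passed by edgeR, the same fold rule was applied to the calls of DESeq2 1.42.0, a choice made after seeing the data. Of most lists that did not pass, only the member with the smallest p is named, also a choice made after seeing the data. Some genes that the rule names are not reported here. Alternatives were other scaling factors, other count filters, a fold threshold of 1.5, DESeq2, the replicate number as a block, other receptor sets and leaving out each mouse. Alternatives added after seeing the data were limma voom, DESeq2 with a block or with a mouse left out, and libraries with Xist reads as a covariate or left out. Lists of brain, tooth enamel, glucocorticoid response, acute phase and sex-linked genes, and the pseudogene share of receptor counts, were added after seeing the data.

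The code was tested on counts simulated from the means, library sizes and trended dispersions of the sFlt1 against control comparison. The simulation held 19899 genes, with 50 changed at each fold. Genes were drawn independently, without spread of their dispersions around the trend, and changed genes lay above a minimum mean CPM. The rates of recovery and of unchanged genes called may therefore not carry over to the real data. edgeR recovered 10% of genes changed 2-fold, 50% of those changed 4-fold, 86% of those changed 8-fold and 96% of those changed 16-fold, and 6 of its 127 calls were unchanged genes. DESeq2 recovered 16%, 64%, 96% and 94% at these folds, and 55 of its 190 calls were unchanged genes. The receptor-only fit recovered 41 of 50 receptors changed 8-fold. With genes simulated independently, camera called the 1 list raised 2-fold and 0 of 31 unchanged lists. In the real data the estimated correlation was 0.895 for mature neuron markers and 0.794 for cell cycle genes. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists here.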

Results

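The data are gene counts from the olfactory epithelium of 6 c57Bl6/ICR crossbred mice at 3 months of age. The 3 sFlt1 mice carried a Camk2a-tTA driver and a tet-regulated transgene for soluble Flt1, a decoy receptor that binds VEGF, and tetracycline was withdrawn at embryonic day 13.5. Their olfactory bulbs, the targets of olfactory sensory neurons, measured 28%, 29% and 14% of normal by MRI at 2 months for replicates 1, 2 and 3. The comparison asks how the sensory tissue of mice with a degenerated bulb differs from that of 3 controls. Library totals were 32194320, 28832424 and 46444862 counts for control replicates 1, 2 and 3 and 30300680, 41669010 and 44449029 counts for sFlt1 replicates 1, 2 and 3. All mice are labelled male, but control replicate 1 and sFlt1 replicate 3 had Xist at 709.9 and 523.7 CPM. Their summed Y-linked genes Ddx3y, Eif2s3y and Kdm5d were at 0.089 and 0.115 CPM, while Uty, also Y-linked, was at 4.42 and 0.896 CPM. The other 4 libraries had Xist at 0.371 CPM or less, the summed genes at 134 CPM or more and Uty at 36.2 CPM or more.

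Flt1 (ENSMUSG00000029648, chromosome 5, 147498414 to 147662821, GRCm39), of which the transgene encodes a soluble form, was at 5.86 ± 4.53 CPM in controls and 6.19 ± 3.72 CPM in sFlt1 mice (SD, n = 3 each). Its log2 fold change was 0.08 (SE 0.70, edgeR adjusted p = 0.97). The counts do not separate transgene reads from those of the endogenous gene. The estimate was -0.11 without control replicate 1, -0.26 without control replicate 2, 0.92 without control replicate 3, 0.47 without sFlt1 replicate 2 and -0.43 without sFlt1 replicate 3.

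Markers of mature olfactory sensory neurons fell as a list, while those of dividing cells and neuronal precursors rose. All 17 mature neuron markers had lower estimates in sFlt1 mice, with a median log2 fold change of -1.14. Omp (chromosome 7, 97792566 to 97794709), the olfactory marker protein, was at 3497 ± 616 CPM in controls and 1383 ± 952 CPM in sFlt1 mice (SD, n = 3 each). In sFlt1 replicates 1, 2 and 3 it stood at 1317, 2366 and 465.8 CPM. Adcy3, the adenylyl cyclase of odor transduction, had a log2 fold change of -1.15 (SE 0.46) and Gnal, its G protein subunit, -1.12 (SE 0.48). The channel subunit Cnga2 had -0.92 (SE 0.38), and Ric8b, an exchange factor for that G protein, -1.33 (SE 0.38). The list passed camera (adjusted p = 4.6e-09, and adjusted p = 0.57 with an estimated correlation), and adjusted over the list alone 0 members passed by edgeR. The median was -1.75 without sFlt1 replicate 2, where Adcy3, Gnal and Cnga2 were at -1.75, -1.69 and -1.44, and -0.73 without both libraries that had Xist reads.

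Synaptic vesicle genes fell, with 9 of 10 lower and a median log2 fold change of -1.35. Snap25, a membrane fusion protein, was at 497.1 ± 308 CPM in controls and 151 ± 32.7 CPM in sFlt1 mice (SD, n = 3 each). Rab3a, a vesicle GTPase, was at 132 ± 46.5 against 52.05 ± 11.3 CPM. The list passed camera (adjusted p = 5.3e-07, and adjusted p = 0.48 with an estimated correlation), and adjusted over the list alone 9 members passed by edgeR. Control replicate 3 held Snap25 at 853.1 CPM and stood apart in brain transcripts, with Gad1, a GABA-synthesis enzyme, at 568.6 CPM against 27.4 CPM or less in the other 5 libraries. The log2 fold change of Snap25 was -1.72, and -1.08 without that mouse.

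Genes linked to odor-driven activity fell, with all 6 members lower and a median log2 fold change of -1.70. The list does not record in which direction activity moves each member, so the fall is not read as lower activity. Pcp4l1 (chromosome 1, 171000831 to 171023837) stood at 679.6, 973 and 790.6 CPM in controls and 228.2, 248.7 and 212.3 CPM in sFlt1 mice, a log2 fold change of -1.83 (SE 0.23, edgeR adjusted p = 0.42, DESeq2 adjusted p = 4.6e-08). The calcium-binding S100a5 was at 1125 ± 320.0 CPM in controls and 344.2 ± 231 CPM in sFlt1 mice (SD, n = 3 each). Mature neuron markers fell in the same libraries, with a median of -1.14. Relative to their mean, differences were -1.35 for Kirrel2, -0.72 for Lrrc3b and -0.62 for S100a5, without overlap between the groups. They were -0.48 for Pcp4l1, -0.019 for Sema7a and 0.71 for Kirrel3, which overlapped. The list passed camera (adjusted p = 1.1e-05, and adjusted p = 0.48 with an estimated correlation), and adjusted over the list alone 4 members passed by edgeR. Of the authors' own marker panel, all 12 genes under its activity heading had lower estimates. Log2 fold changes ran from -1.04 for Eml5 to -3.01 for Nphs1, with Rasgrp4 at -2.62. The panel as a whole was not compared relative to the mature neuron markers, whose median was -1.14. Its Slc17a6, at -1.24, is also one of these markers. A panel chosen by the study is not independent evidence of its direction.

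Axon guidance and sorting genes did not pass as a list, with 13 of 19 lower and a median log2 fold change of -0.29 (camera adjusted p = 0.15). Epha5 (chromosome 5, 84202620 to 84565241), a receptor for ephrin-A ligands, was at 119.4, 153.9 and 155.3 CPM in controls and 39.8, 50.9 and 39.2 CPM in sFlt1 mice. Its log2 fold change was -1.72 (SE 0.20, edgeR adjusted p = 0.42, DESeq2 adjusted p = 6.4e-07), and it was the 1 member that passed when adjusted over the list alone. The adhesion gene Ncam1 had -0.63 (SE 0.23). Without sFlt1 replicate 2 the list passed, with a median of -0.48, and without sFlt1 replicate 1 the median was -0.18 and did not pass.

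Cell cycle genes rose, with all 16 estimates above 0 and a median log2 fold change of 1.21. Ccna2, a cyclin, was at 7.71 ± 3.06 CPM in controls and 18.01 ± 0.67 CPM in sFlt1 mice (SD, n = 3 each), while Pcna, a replication clamp, had a log2 fold change of 0.24 (SE 0.17). The list passed camera (adjusted p = 1.8e-10, and adjusted p = 0.48 with an estimated correlation), and adjusted over the list alone 5 members passed by edgeR. Globose basal cell and neuronal precursor markers rose, with 9 of 10 higher and a median of 0.97 (camera adjusted p = 0.00029, and adjusted p = 0.48 with an estimated correlation). Adjusted over the list alone 5 of them passed by edgeR. Among them the transcription factor Insm1 had a log2 fold change of 1.44 (SE 0.36) and Sox11 1.68 (SE 0.44). Immature neuron markers rose, with 8 of 11 higher and a median of 0.64 (camera adjusted p = 0.0016, and adjusted p = 0.63 with an estimated correlation). Gap43, a growth cone protein, was at 57.6 ± 32.7 against 117.6 ± 11.6 CPM and Gng8 at 10.4 ± 7.54 against 24.9 ± 1.84 CPM (control against sFlt1, SD, n = 3 each). Dpysl3 had a log2 fold change of 1.33 (SE 0.37). Horizontal basal cell markers rose, with all 6 higher and a median of 0.94 (camera adjusted p = 0.0016, and adjusted p = 0.48 with an estimated correlation). Krt5, a keratin of these reserve stem cells, was at 51.7 ± 17.3 against 89.1 ± 35.5 CPM and Icam1 at 3.10 ± 1.25 against 9.02 ± 4.19 CPM (control against sFlt1, SD, n = 3 each). Adjusted over the list alone, 0 immature neuron and 0 horizontal basal cell markers passed by edgeR. Without control replicate 1 the log2 fold changes of Gap43 and Gng8 were 1.60 and 2.07, each over 1.5 times the value with all mice, and without sFlt1 replicate 1 Krt5 was at 0.52 against 0.79. Without both libraries that had Xist reads, the medians were 1.91 for cell cycle genes and 1.04 for immature neuron markers.

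**Figure D1:**
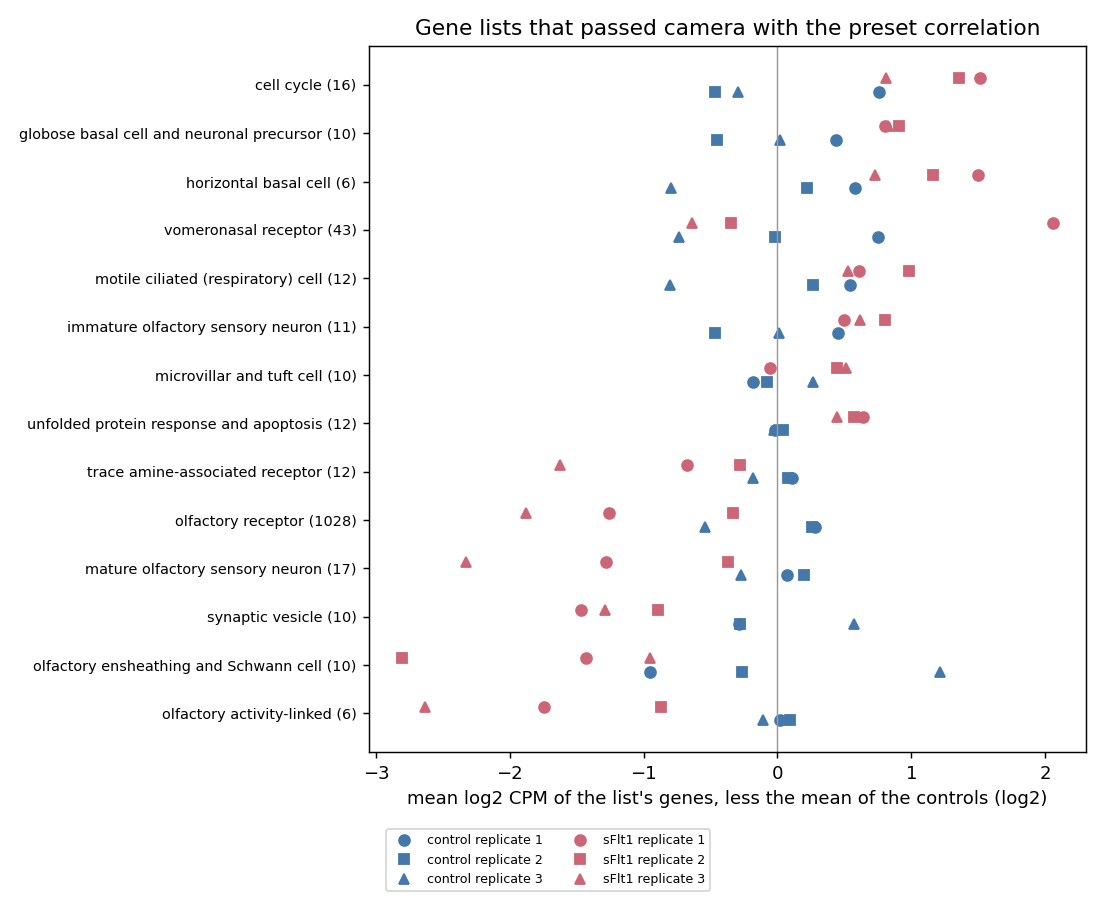
Mean log2 CPM of each gene list that passed camera with the preset correlation, less the mean of the 3 controls (x axis, log2), with 1 point per mouse (circle, square and triangle for replicates 1, 2 and 3) and the number of tested genes in brackets. The sFlt1 libraries lay at -1.28, -0.37 and -2.33 for the mature neuron markers (replicates 1, 2 and 3), all below the controls, while the groups overlapped for the vomeronasal, olfactory receptor, ensheathing, ciliated and microvillar lists.

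Markers of other cell types of the nose moved in both directions. Sustentacular cell markers, from the supporting cells of this epithelium, did not pass, with 6 of 10 lower and a median log2 fold change of -0.08 (camera adjusted p = 0.83). Their Cbr2 was at 1716 ± 393 CPM in controls and 2406 ± 273 CPM in sFlt1 mice (SD, n = 3 each). The list's direction turned without control replicate 2, at 0.12, and without sFlt1 replicate 1, at 0.058. Motile ciliated cell markers rose, with 10 of 12 higher and a median of 0.70 (camera adjusted p = 0.0058, and adjusted p = 0.80 with an estimated correlation). The dynein gene Dnah5 had a log2 fold change of 1.34 (SE 0.48) and Tmem212, a gene of ciliated cells, 1.98 (SE 0.42). The list did not pass without control replicate 3, at 0.40, or without sFlt1 replicate 2, at 0.52. Microvillar and tuft cell markers rose, with 8 of 10 higher and a median of 0.50 (camera adjusted p = 0.0098, and adjusted p = 0.69 with an estimated correlation). Their Cftr, a chloride channel gene (chromosome 6, 18170686 to 18322767), was at 23.8 ± 1.04 against 45.1 ± 2.10 CPM (control against sFlt1, SD, n = 3 each). This list did not pass without control replicate 1, at 0.51, without sFlt1 replicate 2, at 0.52, without sFlt1 replicate 3, at 0.34, or without both libraries that had Xist reads, at 0.34. Adjusted over the list alone, 1 ciliated and 1 microvillar member passed by edgeR.

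Ensheathing glia and Schwann cell markers fell, with 9 of 10 lower and a median log2 fold change of -1.47 (camera adjusted p = 0.00031, and adjusted p = 0.63 with an estimated correlation). Adjusted over the list alone, 4 members passed by edgeR. The mean log2 CPM of the list in control replicate 3, the library with brain transcripts, lay 1.22 above the mean of the controls, and without that mouse the median was -0.58. It was -2.43 without both libraries that had Xist reads. Unfolded protein response and apoptosis genes rose, with 10 of 12 higher and a median of 0.34 (camera adjusted p = 0.0097, and adjusted p = 0.48 with an estimated correlation). Their members differed in direction. The stress factor Atf3 (chromosome 1, 190902493 to 190950236) was at 3.74 ± 3.08 against 36.8 ± 9.49 CPM, while Atf5, another factor of this family, was at 1391 ± 364 against 855 ± 306 CPM (control against sFlt1, SD, n = 3 each). Adjusted over the list alone, 1 member passed by edgeR, and without sFlt1 replicate 1 the median was 0.22. Atf5 had a log2 fold change of -0.70, and -0.47 without sFlt1 replicate 3. Vomeronasal receptors rose, with 39 of 43 higher and a median of 0.83 (camera adjusted p = 0.042, and adjusted p = 0.84 with an estimated correlation), and adjusted over the list alone 0 passed. The list reversed without sFlt1 replicate 1, at -0.57, and did not pass without control replicate 2, at 0.76, or without control replicate 3, at 0.58. It was at 1.65 without control replicate 1, at 1.43 without sFlt1 replicate 2 or sFlt1 replicate 3, and at 1.62 without both libraries that had Xist reads. Vmn1r180 had a log2 fold change of 3.27 (SE 0.66), from 0.123 ± 0.054 CPM in controls (SD, n = 3), and Vmn2r97 0.05 (SE 0.69). Vmn2r97 turned to -0.13 without control replicate 1, -0.020 without control replicate 3, -0.27 without sFlt1 replicate 1 and -0.22 without sFlt1 replicate 2, and was at 0.37 without control replicate 2 and 0.51 without sFlt1 replicate 3.

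The remaining lists did not pass, with camera adjusted p-values from 0.13 to 0.94 and 0 members of each passing when adjusted over the list alone by edgeR. Median log2 fold changes of immune lists were 0.40 for macrophages, 1.09 for neutrophils, 0.64 for T and NK cells and 0.33 for B and plasma cells, where camera gave the direction as down. Members with the smallest p were Cd68 at 1.47, S100a9 at 1.84, Cd4 at 1.01 and Mzb1 at 0.97. Endothelial cells had a median of 0.23, pericytes and smooth muscle 0.25, fibroblasts 0.62, the VEGF axis 0.25 and erythroid genes -0.47, with Cldn5 at -1.25, Myh11 at 2.15, Dcn at 0.56, Dll4 at 1.30 and Hba-a2 at -0.81. Nasal glands had 0.50, bone and cartilage 0.73, skeletal muscle 1.66 and guanylate cyclase D neurons 0.21, with Dmbt1 at 2.76, Ibsp at 1.12, Mylpf at 1.18 and Cnga3 at 1.35. Hypoxia genes had 0.35, interferon genes -0.23 and immediate early genes 0.12 with a mean of -0.015 and a test direction of down, with Ldha at 0.70, Ifit1 at -1.45 and Npas4 at -3.17. Single mice decided several of these. Glands (0.85), macrophages (0.69) and endothelial cells (0.55) passed without sFlt1 replicate 2, and macrophages (0.58) without control replicate 3. Neutrophils (1.55) and fibroblasts (1.09) passed without sFlt1 replicate 3, fibroblasts (1.83) without control replicate 1, and B and plasma cells (-1.48) and erythroid genes (-1.88) without sFlt1 replicate 1. The hypoxia median was 0.53 without control replicate 3, 0.59 without sFlt1 replicate 2 and 0.12 without sFlt1 replicate 3. The interferon median turned to 0.075 without control replicate 1. It was -0.49 without control replicate 2, -0.53 without sFlt1 replicate 1, -0.087 without sFlt1 replicate 2 and -0.15 without sFlt1 replicate 3. Medians turned without sFlt1 replicate 1 for glands (-0.050), neutrophils (-0.23), endothelial cells (-0.00074), pericytes (-0.17), bone (-0.68) and skeletal muscle (-2.60). They turned without sFlt1 replicate 3 for erythroid genes (0.035), guanylate cyclase D neurons (-0.47), the VEGF axis (-0.058) and immediate early genes (-1.39). They also turned without control replicate 1 for B and plasma cells (-0.018) and immediate early genes (-0.18), without control replicate 2 for immediate early genes (-0.057) and without control replicate 3 for pericytes (-0.047). Named members moved too. Without sFlt1 replicate 1, S100a9 was at 0.079, Hba-a2 at -2.38, Ibsp at 0.46, Ldha at 0.42 and Mylpf at -0.99. Without sFlt1 replicate 2, Hba-a2 was at -0.51, and without sFlt1 replicate 3 it was at -0.29, with Myh11 at 0.94, Dll4 at 0.50 and Cnga3 at -0.025. Without control replicate 1, Mzb1 was at 2.58, Cd4 at 1.74, Ibsp at 2.90 and Hba-a2 at -0.35. Without control replicate 2, Mzb1 was at 0.42, Ibsp at 0.71 and Mylpf at 1.89, and without control replicate 3, Cd4 was at 0.58, Cldn5 at -0.44, Ibsp at 0.66 and Npas4 at -1.32.

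Gene by gene, edgeR passed 0 of 19899 genes (smallest adjusted p = 0.42), with 2204 at an unadjusted p under 0.05, 963 higher and 1241 lower. DESeq2 passed 426 genes, 121 higher and 305 lower, and limma voom passed 0. The groups did not overlap for 18.3% of genes, where chance gives 10% on average over all splits. A single split can lie far from that average when genes move together. The share was not computed for the other splits, so no conclusion is drawn from it. Outside the receptors, the higher DESeq2 calls with the largest folds were Sbpl, Mettl21e, Cd109, Plin4, Lyz1, Pklr, Atf3 and Tnfsf18, with DESeq2 log2 fold changes from 2.83 to 5.47. The lower ones were Th, Tmem132d, Gabra2, Prss56, Cpne4, Brinp3, Nrsn1 and Htr7, from -5.90 to -4.51. Without control replicate 3 the edgeR log2 fold changes were nearer 0, at -3.62 for Th, -3.06 for Tmem132d, -2.63 for Gabra2, -2.36 for Cpne4, -2.92 for Brinp3, -2.56 for Nrsn1 and -2.82 for Htr7. Without sFlt1 replicate 3 edgeR gave -7.06 for Brinp3, 2.29 for Cd109 and 2.17 for Plin4, against -4.69, 3.93 and 3.76 with all mice. Th, a dopamine-synthesis enzyme found in bulb interneurons, was at 5.10, 9.30 and 90.4 CPM in controls and 0.175, 0.240 and 1.31 CPM in sFlt1 mice. Gabra2, a GABA receptor subunit, was at 3.08, 5.95 and 58.4 CPM in controls and 0.772, 0.218 and 1.20 CPM in sFlt1 mice. Of the 203 lower calls outside the receptors 164 were highest in control replicate 3, and of the 121 higher calls 73 were highest in sFlt1 replicate 3. The DESeq2 count was 814 without control replicate 1, 186 without control replicate 3, 233 without sFlt1 replicate 1, 1070 without sFlt1 replicate 2 and 718 without sFlt1 replicate 3. edgeR passed 1 gene, Gm44964, without control replicate 2, a name seen only after the test. The authors' deposited table lists 394 genes at an adjusted p under 0.05, and 378 of them are among the 426.

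**Figure D2:**
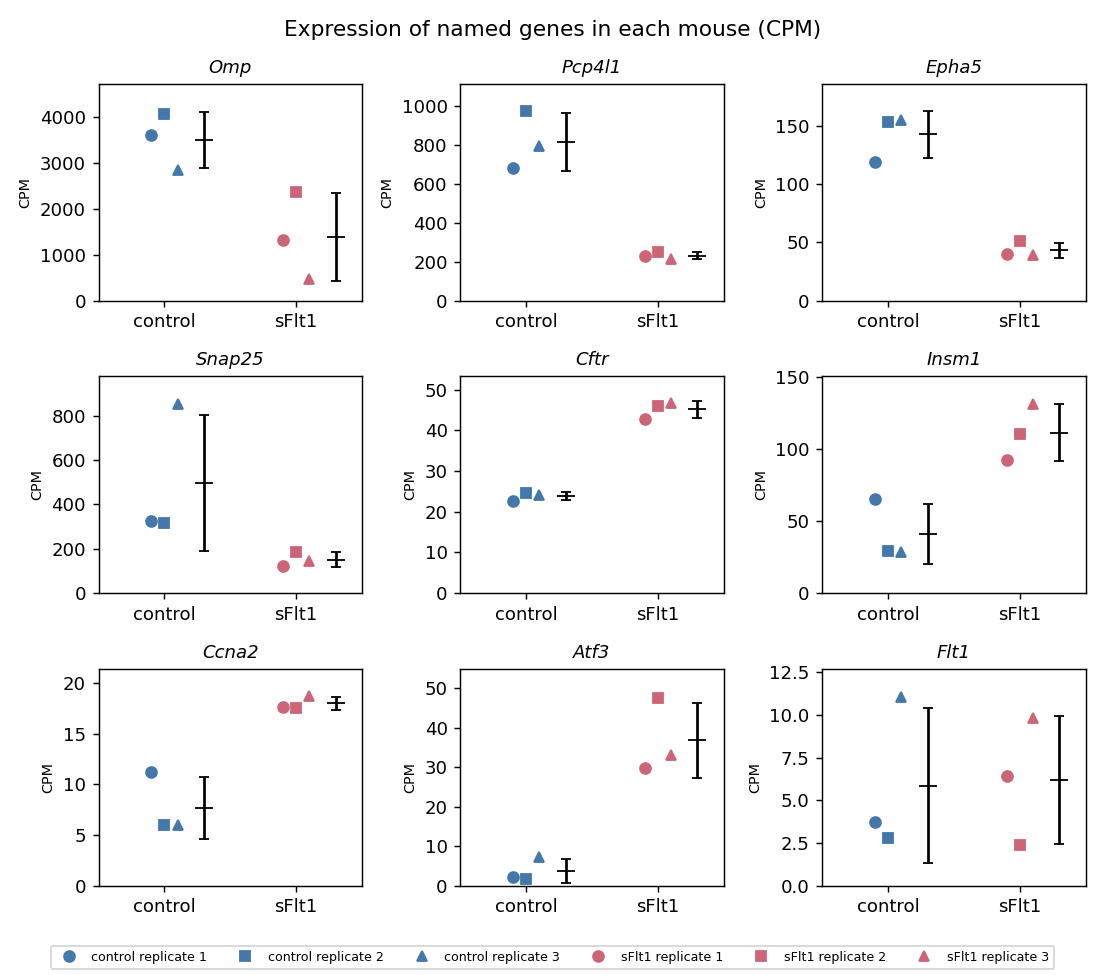
CPM (y axis, linear from 0) of 9 named genes in each control and sFlt1 mouse, with a circle, square and triangle for replicates 1, 2 and 3 and bars for mean and SD (n = 3). Pcp4l1, Epha5 and Cftr did not overlap between the groups, Omp ranged from 465.8 to 2366 CPM among sFlt1 mice, and Flt1 overlapped.

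Olfactory receptor genes fell as a list, with 916 of 1028 lower and a median log2 fold change of -1.09 beside -1.14 for the mature neuron markers. Olfr522 (chromosome 7, 139739912 to 139744677) was at 12.1, 17.7 and 12.3 CPM in controls and 1.97, 1.96 and 2.05 CPM in sFlt1 mice, a log2 fold change of -2.81 (SE 0.32). Olfr1019, Olfr506, Olfr728 and Olfr1309 had -3.18, -2.37, -2.17 and -2.99. The higher receptors with the smallest p were Olfr1249, Olfr1214, Olfr161, Olfr944 and Olfr388-ps1, whose sFlt1 means lay between 0.349 and 2.57 CPM. The list passed camera (adjusted p = 1.8e-31, and adjusted p = 0.48 with an estimated correlation), and its median was -0.70 without both libraries that had Xist reads. Single receptors passed in 0 cases by edgeR, also when adjusted over the list alone (smallest adjusted p = 0.053), with 285 at an unadjusted p under 0.05, 279 of them lower. DESeq2 passed 102 receptors, all lower, and limma voom 0. The groups did not overlap for 31.6% of receptors, where chance gives 10% on average over all splits. Receptors moved together (estimated correlation 0.36) and the share was not computed for the other splits, so no conclusion is drawn from it. The DESeq2 count was 33 without control replicate 2, 51 without sFlt1 replicate 1 and 313 without sFlt1 replicate 2. Trace amine-associated receptors, a small receptor family of the same epithelium, fell with 9 of 12 lower and a median of -0.81 (camera adjusted p = 0.0069, and adjusted p = 0.48 with an estimated correlation). Taar3 had a log2 fold change of -1.36 (SE 0.43) and Taar6 0.19 (SE 0.71), which turned to -0.25 without sFlt1 replicate 1 and -0.011 without sFlt1 replicate 2. Taar6 was at 0.36 without control replicate 2, 0.096 without control replicate 3 and 0.68 without sFlt1 replicate 3. Adjusted over the list alone 0 members passed by edgeR. That list did not pass without sFlt1 replicate 3, at -0.44, or without both libraries that had Xist reads, at -0.44, and was at -1.27 without sFlt1 replicate 2.

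Receptor counts made up 0.648%, 0.622% and 0.420% of all counts in control replicates 1, 2 and 3 and 0.246%, 0.491% and 0.170% in sFlt1 replicates 1, 2 and 3. The 95% Wilson intervals were 0.418% to 0.422% for control replicate 3 and 0.489% to 0.494% for sFlt1 replicate 2, the pair in which the groups overlapped. The group means were 0.563 ± 0.125% and 0.302 ± 0.168% (SD, n = 3 each; exact permutation p = 0.2, two-sided, adjusted 0.3 over 6 measures). Summed receptor log2 CPM less the mean log2 CPM of mature neuron markers was 3.38 ± 0.08 in controls and 3.68 ± 0.31 in sFlt1 mice (SD, n = 3 each; exact p = 0.2, adjusted 0.3), and the difference of 0.30 was 0.12 without sFlt1 replicate 3 and 0.58 relative to Omp alone. After thinning, 1099 ± 18.4 receptors were detected in controls and 1134 ± 10.3 in sFlt1 mice (SD, n = 3 each; exact p = 0.1, the smallest possible, adjusted 0.3). That difference of 34.2 was 14.7 when 5 or more counts were asked for (exact p = 0.5), 12 without thinning (exact p = 0.6) and -0.17 among receptors with a mean of 10 or more counts (exact p = 1). The effective number of receptors, from the entropy of their counts, was 550 ± 105 against 470.3 ± 73.2 (exact p = 0.3, adjusted 0.36). That difference of -79.5 was -44.6 without control replicate 1, -139.9 without control replicate 3, -120.4 without sFlt1 replicate 2 and -49.8 without sFlt1 replicate 3.

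**Figure D3:**
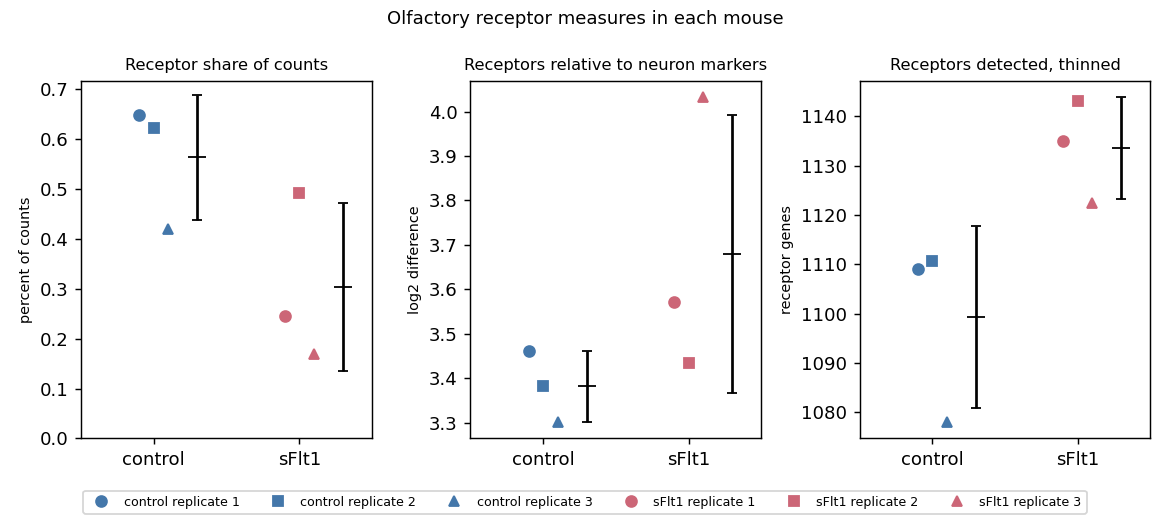
Receptor share of counts (percent, axis from 0), summed receptor log2 CPM less the mean log2 CPM of mature neuron markers (axis not from 0), and receptor genes detected after thinning (axis not from 0), with a circle, square and triangle for replicates 1, 2 and 3 and bars for mean and SD (n = 3). The share overlapped between the groups, and the number detected was 1078 to 1111 in controls and 1123 to 1143 in sFlt1 mice.

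Within the receptor repertoire, with the total receptor level set equal, the relatively higher receptors with the smallest p were Olfr1249, Olfr944, Olfr1214, Olfr75-ps1 and Olfr161. Their log2 fold changes were 3.15, 3.12, 2.68, 2.94 and 3.23. The relatively lower ones were Olfr348, Olfr107, Olfr1154, Olfr97 and Olfr358, with -2.64, -2.37, -2.15, -2.34 and -2.09, and Olfr161 was at 2.02 without sFlt1 replicate 3. edgeR passed 0 of 1059 receptors (smallest adjusted p = 0.081), with 141 at an unadjusted p under 0.05, 88 higher and 53 lower. DESeq2 passed 39, 31 higher and 8 lower. The 31 had a median control level of 0.271 CPM against 2.66 CPM for all receptors, and 14 of them are pseudogene models. The authors' deposited table on doubly normalized receptor counts lists 36 at an adjusted p under 0.05, and 34 of them are among the 39. Both start from the same counts, so the overlap is not independent, and the authors first scaled theirs by their own factor per sample. The DESeq2 count was 13 without control replicate 2, 0 without control replicate 3 and 11 without sFlt1 replicate 1. edgeR passed 1 (Olfr427) without control replicate 2, 3 (Olfr1214, Olfr944 and Olfr461) without sFlt1 replicate 3, and 41 when both libraries with Xist reads were left out, a choice made after seeing the data.

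Class I receptors, which project to a dorsal domain of the bulb, had a mean log2 fold change 0.39 above that of class II receptors in the receptor-only fit, with 115 and 944 tested (camera p = 0.037, and p = 0.64 with an estimated correlation). The class I share of receptor counts was 6.16%, 5.25% and 5.05% in control replicates 1, 2 and 3 and 5.05%, 4.17% and 10.02% in sFlt1 replicates 1, 2 and 3. The 95% Wilson interval of the last was 9.81% to 10.23%. The group means were 5.49 ± 0.59% and 6.41 ± 3.15% (SD, n = 3 each; exact permutation p = 1, two-sided). Their difference of 0.925 percentage points was 1.61 without sFlt1 replicate 1, 2.04 without sFlt1 replicate 2 and -0.878 without sFlt1 replicate 3. The difference between the classes was -0.17 without sFlt1 replicate 3, 0.61 without sFlt1 replicate 1 and 0.74 without sFlt1 replicate 2, and it did not pass without control replicate 2, at 0.28. It was -0.10 without both libraries that had Xist reads.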

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

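The Xist, limma voom and DESeq2 leave-out and block alternatives were chosen after seeing the data. Of 1940 alternative values of 129 results, 1744 kept the direction of their test and their side of the threshold or, for 64 counts among them, lay within 1.5 times the count reported. Among the 1744 were 12 list medians that crossed 0 while the direction of the camera test did not turn. Values per mouse were compared by direction only. No named gene or receptor passed by edgeR with all mice, so for these keeping a side meant staying above the threshold. The 1744 is therefore no measure of how firm the results are. The cause of the changes below was not tested. By edgeR 0 genes and 0 receptors passed under the other scalings, filters, fold threshold, replicate block and Xist alternatives. With single mice left out edgeR passed 0 to 1 genes, 0 receptors, and 0 to 3 receptors relative to other receptors, and 41 of the latter without both Xist libraries. DESeq2 gave 426, 102 and 39 for these counts. With single mice left out it gave 186 to 1070, 33 to 313 and 0 to 56. It passed 775 genes with Xist as a covariate and 1215 without both Xist libraries. The 31 receptors that DESeq2 placed relatively higher had a median of 0.271 CPM in controls, and whether depth limits such calls was not tested.

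Same-numbered mice deviated with correlations of 0.026, 0.25 and 0.36, and control replicate 1 correlated best with sFlt1 replicate 2, at 0.29, so the numbers were not taken to pair mice. With the replicate block, DESeq2 passed 1551 genes and 286 receptors and camera 17 lists, with nasal glands, macrophages and erythroid genes added, and the class I difference was 0.28 and passed. Vmn2r97 was at -0.22 and Taar6 at -0.20 under the block, and at -0.25 and -0.23 with receptor-free scaling as well.

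Of the 14 lists, 0 passed with an estimated correlation and 0 with fry. Of all 32 lists 4 passed fry's test for changes in either direction, namely unfolded protein response, activity-linked, microvillar and axon guidance genes. Vomeronasal (0.90) and trace amine-associated receptors (-0.75) did not pass with a CPM filter, nor did vomeronasal receptors with Xist as a covariate (0.78). The class I difference of 0.39 did not pass with an estimated correlation. With fry, which tests class I receptors against no change and not against class II, class I did not pass. The difference between the classes was 0.37 and did not pass with a CPM filter, and was -0.10 without both Xist libraries and -0.17 to 0.74 with single mice left out. The class I share difference was -0.878 to 2.04 percentage points with single mice left out. The difference in receptors detected was -0.167 among receptors with a mean of 10 or more counts, 14.7 at 5 or more counts after thinning and 12 without thinning. Flt1 had log2 fold changes of -0.43 to 0.92 with single mice left out, -0.0017 with Xist as a covariate, -0.66 without both Xist libraries and -2.7e-06 with limma voom. Vmn2r97 and Taar6 were at -0.25 and -0.20 with Xist as a covariate and at -0.27 and -0.30 with limma voom. Without both Xist libraries Hba-a2 was at 0.15 and Cnga3 at -0.22.

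With single mice left out, log2 fold changes ranged from -0.27 to 0.51 for Vmn2r97, -0.25 to 0.68 for Taar6, -0.99 to 1.89 for Mylpf and -0.025 to 1.84 for Cnga3. List medians, in lists whose test direction turned, ranged from -0.57 to 1.65 for vomeronasal receptors, -0.18 to 0.12 for sustentacular cells, -0.050 to 0.85 for glands and -0.23 to 1.58 for neutrophils. They ranged from -1.48 to 0.84 for B and plasma cells, 0.017 to 0.99 for T and NK cells, -0.00074 to 0.55 for endothelial cells, -0.17 to 0.60 for pericytes and -0.68 to 1.43 for bone. They ranged from -2.60 to 3.67 for skeletal muscle, -0.47 to 0.64 for guanylate cyclase D neurons, -1.39 to 0.99 for immediate early genes and -0.058 to 0.49 for the VEGF axis. In lists that did not pass with all 6 mice, other medians ranged from 0.12 to 0.59 for hypoxia, -0.53 to 0.075 for interferon, 0.18 to 0.69 for macrophages, 0.031 to 1.83 for fibroblasts, -1.88 to 0.035 for erythroid and -0.48 to -0.18 for axon guidance genes. Without both Xist libraries the medians were 0.48 for B and plasma cells, 0.040 for endothelial cells, 0.41 for erythroid genes, -0.62 for guanylate cyclase D neurons, 0.080 for the VEGF axis, 0.25 for interferon genes and 0.0099 for hypoxia genes. Lists that did not pass with all 6 mice but passed without both Xist libraries were fibroblasts (2.31), bone and cartilage (1.91), neutrophils (1.62), T and NK cells (1.17) and immediate early genes (-1.75). With a CPM filter the medians were 0.37 for immediate early genes and -0.14 for the VEGF axis. B and plasma cells and immediate early genes were at -0.73 and -0.070 with the replicate block and at -0.093 and -0.55 with Xist as a covariate.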

Other observations

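The tests of dissection, scaling and sex for the neuron markers and of tissue mixture for the Xist reads were chosen only after the results were seen, as were the added gene lists and the genes compared with neuron markers. Relative to the mean of the mature neuron markers, Kirrel2, an adhesion gene regulated by odor-driven activity, was at 0.39 ± 0.23 log2 units in controls and -0.96 ± 1.17 in sFlt1 mice (SD, n = 3 each), a difference of -1.35 that was -0.68 without sFlt1 replicate 3. S100a5 was at 1.04 ± 0.30 against 0.42 ± 0.21 and Lrrc3b at -2.69 ± 0.07 against -3.42 ± 0.39. The groups did not overlap for these 3 of 7 genes compared (exact permutation p = 0.1, the smallest possible, for each). Chance separates 10% of genes on average over all splits. Pcp4l1 (exact p = 0.5), Epha5 (exact p = 0.5), Sema7a (exact p = 1) and Kirrel3 (exact p = 0.4) overlapped. Their differences were -0.48, -0.39, -0.019 and 0.71.

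Libraries differed in transcripts of other tissues or states. Amelx, which encodes an enamel protein of the tooth, was at 163.7, 22.4 and 142.6 CPM in control replicates 1, 2 and 3, at 1217 CPM in sFlt1 replicate 1 and at 0 CPM in sFlt1 replicates 2 and 3. The mean log2 CPM of 5 tested enamel genes was 6.18, 4.45 and 5.43 in control replicates 1, 2 and 3 and 8.20, 0.086 and -0.25 in sFlt1 replicates 1, 2 and 3. sFlt1 replicate 3, the mouse with a bulb of 14% of normal, had the highest mean log2 CPM of the glucocorticoid response list (7.49, against 5.46 or less elsewhere) and of the acute phase list (6.29, against 4.28 or less). In it the glial gene Gfap was at 730.7 CPM, Lcn2, an acute phase gene, at 311.9 CPM and Fkbp5, a glucocorticoid target, at 164.2 CPM, against highest values of 118.6, 20.8 and 55.2 CPM elsewhere. Fkbp5 was not confined to that mouse, at 55.2 and 33.2 CPM in sFlt1 replicates 1 and 2 and 19.7, 15.7 and 20.5 CPM in controls. The acute phase gene Hp was at 21.1, 12.3 and 12.8 CPM in sFlt1 replicates 1, 2 and 3 and 4.89, 4.63 and 2.91 CPM in controls. Gfap and Lcn2 overlapped between the groups. Receptor pseudogene models took 1.37 ± 0.16% of receptor counts in controls and 2.19 ± 0.58% in sFlt1 mice (SD, n = 3 each; exact permutation p = 0.1, the smallest possible, adjusted 0.3), and the difference of 0.814 percentage points was 0.490 without sFlt1 replicate 3. The authors' scaling factor for receptors, multiplied by the DESeq2 size factor of 8 mature neuron genes on their marker panel, lay between 1.16 and 1.19 in all 6 libraries.

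The lower level of mature neuron markers in sFlt1 libraries was weighed first. A smaller share of olfactory mucosa in the sFlt1 dissections would lower other olfactory cells too, and scaling moves all genes of a library alike. Scaling cannot change a gap between lists within a library, so it cannot have made the gap between mature neuron and precursor markers. That holds for any values and is not a test. A smaller share of olfactory mucosa is argued against as the whole cause of that gap, though the lists were compared after their directions were seen. Motile ciliated (respiratory) cell markers rose, with a median of 0.70, which such a smaller share could also give. For the fall of the neuron markers itself dissection and scaling stay open, since a separate rise of precursor markers would also widen that gap. Globose basal less mature neuron markers differed by 2.17 log2 units (SE 0.63) and immature less mature neuron markers by 1.97 (SE 0.62). Both were higher in every sFlt1 library than in every control, by more than the 2 SE asked for. Sustentacular less mature neuron markers differed by 1.23 (SE 0.70), which is under 2 SE, and by 0.56 without sFlt1 replicate 3. The neuron median was -1.15 with RLE factors and -1.16 with factors from genes other than receptors, although neuron markers less the median gene overlapped between the groups, at 5.02 in sFlt1 replicate 2 and 4.92 in control replicate 3. An effect of sex that is the same in both groups is argued against, since it would cancel with 1 library with Xist reads in each, but one that differs between the groups stays open, with a median of -0.73 and a mean difference of -0.79 (SE 0.51, n = 2 each) without both libraries, as does, untested, a loss or immaturity of neurons with the degenerated bulb.

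Xist reads with almost no reads of Ddx3y, Eif2s3y and Kdm5d, genes chosen after their values were seen, in 2 libraries labelled male were weighed next. A mixture of male and female tissue is argued against, since the summed level of these genes in the higher of these libraries was 0.078% of the mean of the others. Uty was at 4.42 and 0.896 CPM in control replicate 1 and sFlt1 replicate 3, against 36.2 CPM or more in the others, and at these shares Ddx3y would have had 190.1 and 49.8 counts where 0 were seen, and the source of the Uty reads was not tested. A candidate explanation is that the sex of these mice differs from the label. X-linked genes that escape inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) were highest in the library with Xist reads in 7 of 8 comparisons within its group, the exception being Kdm5c in sFlt1 replicate 3.

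Brain transcripts stood high in control replicate 3, where 15 of 16 genes of a first list, chosen from that library, were highest, with Slc1a2 at 935.3 CPM and Gad1 at 568.6 CPM. Brain tissue in that dissection may account for this. In a second list, chosen before its values were seen, 77.8% of 18 tested genes were highest there, short of the 80% set in advance, and some of its genes were abundant in every library, such as Aqp4 at 405 CPM or more. Less brain tissue carried along from the smaller bulbs of sFlt1 mice also stays open, since the lower of the other controls lay -0.16 log2 units from the highest sFlt1 library on that list, below it but not below every sFlt1 library. The mean log2 CPM of the first list was 4.13, 4.24 and 7.83 in control replicates 1, 2 and 3. It was 2.45, 1.27 and 4.74 in sFlt1 replicates 1, 2 and 3, so sFlt1 replicate 3 lay above control replicates 1 and 2.

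The 6 mice can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes by edgeR the real value was 0 and the highest other 4 (10 splits as large), for receptors 0 and 0 (10 splits), and for receptors relative to other receptors 0 and 1 (10 splits). For gene lists the real value was 14 and the highest other 16 (4 splits as large), for the class I difference 0.39 and 0.75 (9 splits), and for genes by DESeq2 426 and 299 (1 split, the real one).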
